A study of Mus musculus with 14 samples.

How the data were processed

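Germ cells were profiled on Affymetrix expression arrays, 2 biological replicates in each of 7 groups (E9.5, E10.5, E11.5, and females and males at E12.5 and E13.5). Per the labels' protocols, cells from E10.5 to E13.5 came from crosses of BDF1 females with males carrying a stella-EGFP reporter, and were sorted on its fluorescence from genital ridges digested with trypsin. For each of the 14 samples, 5 ng of total RNA, given as the equivalent of 500 cells, was turned into cDNA and amplified by PCR, with 12 cycles for E10.5 to E13.5 and 22 cycles for E9.5. Biotin-labelled cRNA was then hybridized. RNA was isolated with a micro-scale kit for E10.5 to E13.5 and with the standard kit of the same maker for E9.5. Per the series' design text, the E9.5 arrays came from an earlier study, used another strain background and were normalized again together with the others. No sort of the E9.5 cells is described in the sources used here.

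The deposited values were log2 probe set signals, normalized by the authors over all 14 arrays together. The software, background correction and summarization are not given in the sources used here. The log2 scale was read from the range, 0 to 14.04 in the table, and from the steps between the bacterial control probe sets. Between 1.54% and 1.83% of the values of an array were 0. The deposited table held 45101 probe sets, of which 64 were controls. A single gene symbol was listed for 34958 probe sets, several for 932 and none for 9211, and probe sets of the last kinds were left out. Of the probe sets with a single symbol, 34754 matched a RefSeq gene by Entrez identifier. Each of the 18194 genes was represented by its probe set with the highest mean over the arrays of the fit, and 9012 genes had several. For 134 genes the fits of 12 and 14 arrays used different probe sets. No detection calls were used, so levels below the table median of 4.72 are called dim.

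Linear models were fitted with limma 3.58.1 in R 4.3.3, with 1 mean per group and moderated variances with an intensity trend. The 12 arrays from E10.5 to E13.5 gave 10 comparisons and the fit of all 14 arrays gave E10.5 against E9.5. The 11 comparisons were E11.5 against E10.5, each sex at E12.5 against E11.5, each sex at E13.5 against E12.5 and against E10.5, males against females at E12.5 and at E13.5, the change of the sex difference between these ages, and E10.5 against E9.5. Two-sided p-values were adjusted by the Benjamini-Hochberg method within each comparison, and a gene passed with an adjusted p under 0.05. Standard errors and 95% intervals come from the same model, which pools the spread of 2 arrays per group over all groups (6 residual degrees of freedom with 12 arrays, 7 with 14). The number of arrays limits the precision. Among genes above the median level, the median standard error was 0.36 for the change of the sex difference, 0.26 for E10.5 against E9.5 and 0.25 otherwise. Groups of 2 arrays allow no test for outlying arrays.

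Before the data were examined, the groups, comparisons, tests, processing settings to try, 22 gene lists and the rule for named genes were fixed. The lists held 400 entries, 32 of which had no measured gene. They covered germ cell identity, pluripotency, DNA methylation, base excision repair, histone modifiers, S phase, G2 and mitosis, cell cycle inhibitors, germline genes reported to need promoter demethylation, meiosis, male germ cells and piRNA, paternally and maternally expressed imprinted genes, sex check genes, retinoic acid and BMP response, gonadal somatic, male supporting and female supporting cells, endothelium, blood, gut, and immediate early and heat shock genes. Members were counted with p-values adjusted over all genes and adjusted over the list alone. Each list was compared with the other genes by camera (limma) with a preset correlation of 0.01, and again with a correlation estimated from the residuals, with p-values adjusted over the 22 lists of a comparison. The preset gave 77 called lists over the 242 tests, and the estimate 20.

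Genes are named by a fixed rule: up to 10 rising and 10 falling genes of largest log2 change among those with an adjusted p under 0.05, a change of at least 2-fold, both arrays of one group above both of the other and a higher mean above the median gene; up to 4 passing members of each list; and a fixed set of methylation, germ cell and sex check genes. The text takes fewer, in order within the largest changes or within a list, so a list member can stand where a larger change outside the lists does not. Genes named for other reasons are said to have been chosen after their values were seen. Amh and Tdgf1 in the comparison of single E13.5 arrays, the male genes in E13.5 female replicate 1, and Trap1a are of that kind.

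The other settings tried were quantile normalization, median centring, leaving out genes with a mean below that of the median gene (9097 kept), the mean of all probe sets of a gene, no intensity trend, a floor at the 25th percentile, a fit of the compared groups alone, a fit of all 14 arrays, array weights, each array left out in turn, and replicate number as a block. Added after the data were seen were the Gapdh 3' to 5' difference as a covariate, the omission of the arrays where it is above 3, and a replicate block with the numbers of 1 group swapped. Where an array was left out, the lone array of its group was assumed to vary like those of the other groups.

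The tests were checked on simulated data with 200 changed genes, 100 of each size, among 18194, for each comparison. For E11.5 against E10.5, 31% of genes changed 2-fold and 91% of those changed 4-fold were called, and 7.58% of the calls were false. For the sex difference at E13.5, these were 34%, 79% and 0.877%, and for the change of the sex difference 6%, 60% and 0% (0 of 66 calls). Each comparison had a single simulated draw, so these shares carry the chance of that draw. In 20 draws for E13.5 females against E12.5 females, camera called all 20 lists of 31 genes shifted by 0.5 and 0 of 20 unshifted lists. Noise was drawn independently for each gene, so these checks do not cover lists whose genes vary together. Changed genes and shifted lists were drawn from genes above the median level. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.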

Results

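Gene expression was measured in mouse primordial germ cells, the embryonic precursors of eggs and sperm, between embryonic days (E) 9.5 and 13.5. These are the days when the cells reach the genital ridges, lose most DNA methylation and begin to differ between the sexes. The data comprised 14 arrays in 7 groups of 2 biological replicates: E9.5, E10.5, E11.5, E12.5 female, E12.5 male, E13.5 female and E13.5 male. Cells from E9.5, E10.5 and E11.5 were not sexed. Values were log2 signals of 45101 probe sets, from which 18194 genes were tested. The array medians lay between 4.66 and 4.80, and with 2 arrays per group the number of arrays limited the precision. A gene below 4.72, the median of the table, is called dim, and a fold change from or to a dim level is a difference of signal, not a ratio of transcript amounts. Replicates correlated across genes with r between 0.95 and 0.971, and the E10.5 pair was the least alike. Arrays did not always lie nearest to their replicate: the highest r to another group was 0.969 for E9.5, E10.5, E11.5 and E12.5 males, above the r between their replicates (0.962, 0.95, 0.964 and 0.968), and neither E10.5 array was nearest to the other. In a principal component analysis of the 12 arrays from E10.5 to E13.5, the first component held 39.4% of the variance and the next 23.8%. Component 3 held 18.5% and set replicates apart from each other, at 22.2 and -43.6 for E10.5, 18.3 and -21.5 for E11.5, and -13.3 and 6.8 for E13.5 females.

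The arrays carried the signal of germ cells in every group. Dppa3, the germ cell marker whose reporter was used for the sort, lay between 13.23 ± 0.20 (SD, n = 2) at E9.5 and 13.68 ± 0.11 in E13.5 males. Pou5f1, a pluripotency factor of germ cells, lay between 12.45 ± 0.01 and 13.04 ± 0.04 from E10.5 to E13.5. The Y-linked gene Eif2s3y read 10.79 ± 0.16 in E12.5 males and 2.07 ± 0.65 in E12.5 females, and by this gene the sex labels held in all 8 sexed arrays. Its level of 9.66 ± 0.48 at E10.5 and 10.07 ± 0.18 at E11.5 showed that the unsexed samples held male cells. Kdm5d, also Y-linked, read 7.27 ± 0.56 in E13.5 males and 1.6 ± 0.23 in E13.5 females. The probe set for Uty, also Y-linked, read 5.82 ± 0.04 in E13.5 males and 5.51 ± 0.25 in E13.5 females and did not pass at either age. The probe set for Xist lay near 5 in both sexes (5.16 ± 0.12 in E13.5 females and 5.04 ± 0.04 in E13.5 males) and did not separate them. The difference between the 3' and 5' probe sets of Gapdh is a measure of RNA integrity. It was 3.16 and 3.09 in replicate 2 of the E13.5 males and females, and at most 2.53 elsewhere. The same difference for Actb did not set these arrays apart, at 2.94 and 3.09, against 3.29 and 3.13 in replicate 1. The bacterial control dap had its lowest values there, 7.19 and 7.18, so the Gapdh difference alone does not show degraded RNA.

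**Figure D1:**
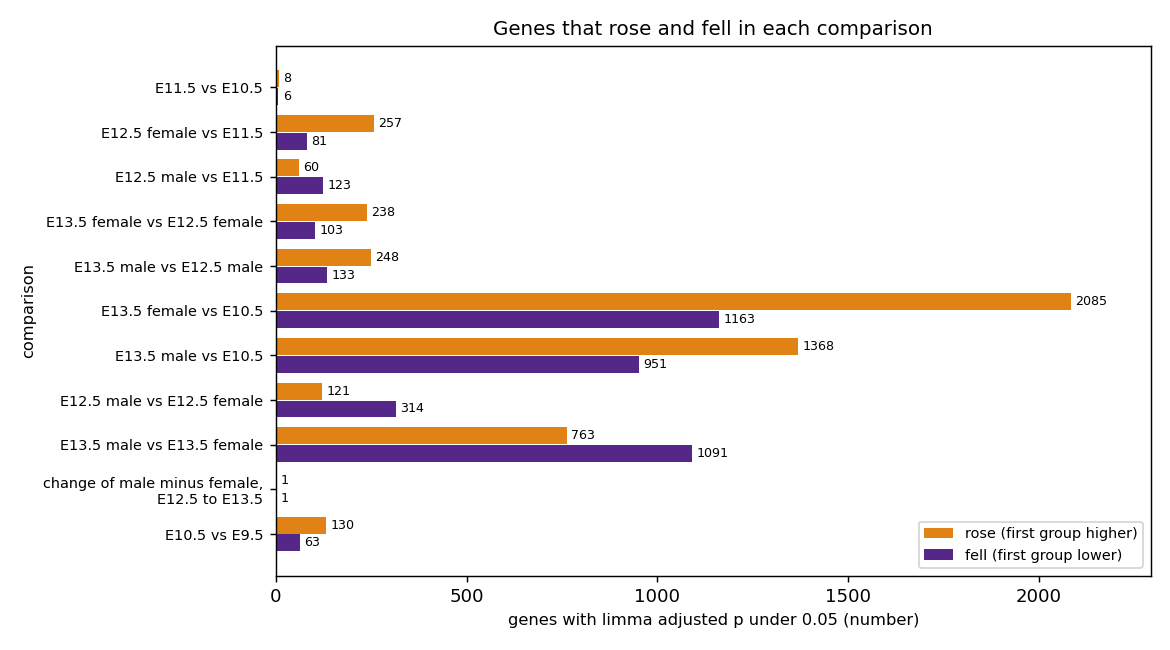
Number of genes (horizontal axis, from 0) that rose or fell with a limma adjusted p under 0.05 in each of the 11 comparisons (vertical axis). The smallest count between adjacent ages was 14, for E11.5 against E10.5, and the E13.5 female comparison with E10.5 gave 3248.

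The comparison of E11.5 with E10.5 asked which genes change as germ cells settle in the genital ridge. Dazl, an RNA-binding protein that germ cells need to enter their sexual program, rose from 9.07 ± 0.16 to 12.08 ± 0.27 (8.06-fold, adjusted p = 0.000111). Ddx4, a helicase of the germ line, rose from 10.76 ± 0.07 to 11.83 ± 0.10, and Ptpn22, a phosphatase, from 5.27 ± 0.31 to 7.43 ± 0.06. Timm8a2, a mitochondrial import gene, rose from a dim 3.95 ± 0.10 to 6.44 ± 0.15. Col3a1, a collagen of mesenchyme, fell from 9.04 ± 0.52 to 6.38 ± 0.04, Actc1, a cardiac actin, from 8.01 ± 0.23 to 5.50 ± 0.36, and Grb10, an imprinted growth regulator, from 9.04 ± 0.06 to 6.88 ± 0.15. With limma, 14 genes passed, of which 8 rose and 6 fell, all at least 2-fold, and 1287 had an unadjusted p under 0.05. Of 20 germline genes reported to need promoter demethylation, 2 rose over all genes tested and 12 adjusted over the list alone (median log2 change 1.1). The list as a whole was higher (camera adjusted p = 1.23e-19, adjusted p = 0.0432 with an estimated correlation). Among 31 meiosis genes 9 rose adjusted over the list alone (camera adjusted p = 3.53e-06, adjusted p = 0.0801 with an estimated correlation), and among 18 genes of male germ cells and piRNAs 4 did. Imprinted genes moved the other way, with 4 of 22 paternally expressed and 3 of 19 maternally expressed genes lower adjusted over the list alone. Markers of other cells were lower beside them: the median change was -0.95 for 10 blood genes (3 lower adjusted over the list alone, camera adjusted p = 3.39e-05, adjusted p = 0.0432 with an estimated correlation) and -0.36 for 18 gonadal somatic genes (3 lower, camera adjusted p = 8.33e-05, adjusted p = 0.0432 with an estimated correlation). Of 11 endothelial genes 1 was lower adjusted over the list alone (camera adjusted p = 0.00231, adjusted p = 0.172 with an estimated correlation).

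Of the 7 genes named for E11.5 against E10.5, Dazl alone passed whichever array was left out. Without E11.5 replicate 1 and without E11.5 replicate 2 the count of passing genes was 1, and without E10.5 replicate 1 and without E10.5 replicate 2 it was 39 and 24. Fitting the 4 compared arrays alone gave 0 genes with limma (737 at an unadjusted p under 0.05), 1 gene passed with array weights, and quantile normalization gave 29.

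**Figure D2:**
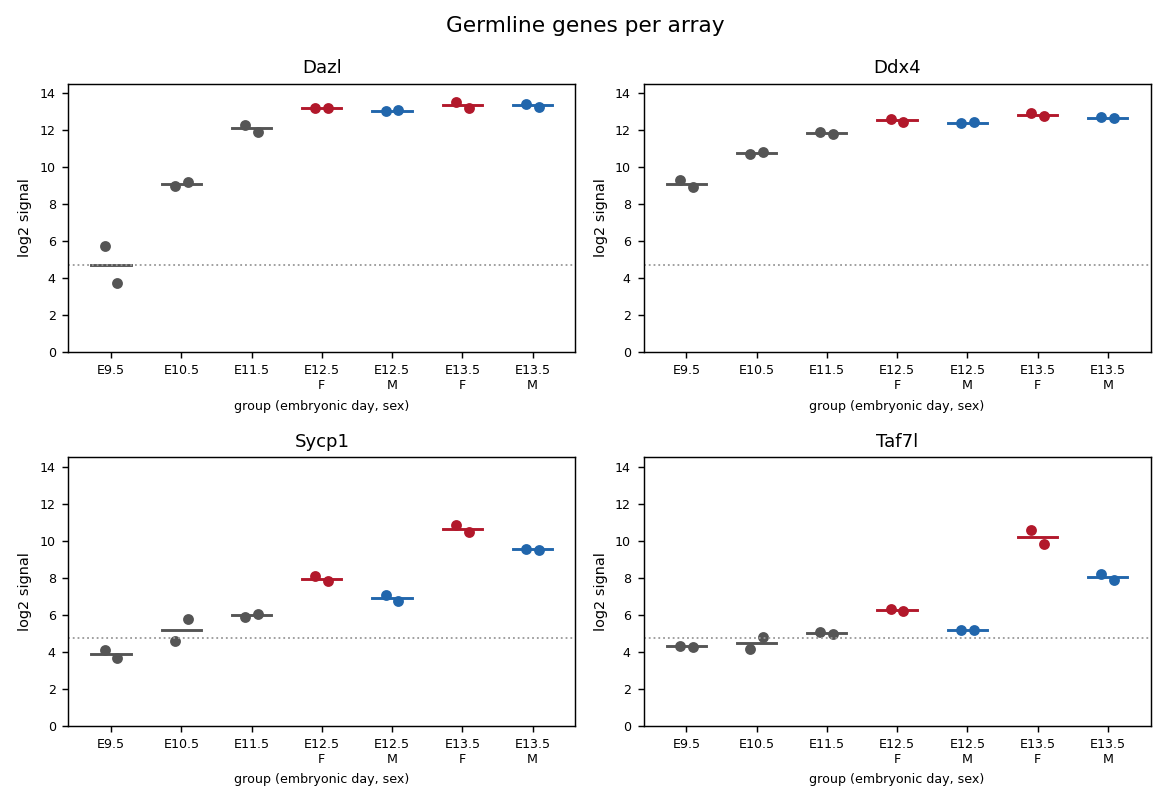
Log2 signal (vertical axes) of Dazl, Ddx4, Sycp1 and Taf7l in each array (points) with the group mean (lines), by group (horizontal axes; F, female; M, male; the dotted line is the table median, 4.72). Dazl read 4.70 at E9.5, 9.07 at E10.5 and 12.08 at E11.5, and Taf7l was highest in E13.5 females at 10.20.

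The comparison of E12.5 females with E11.5 addressed the first day of the female program. Stra8, which retinoic acid induces and which starts meiosis, rose from a dim 4.06 ± 0.55 to 9.95 ± 0.18 (log2 change 5.89, SE 0.67, adjusted p = 0.00254). Cited1, a transcriptional co-activator, rose from a dim 4.04 ± 0.67 to 8.15 ± 0.28. The meiotic cohesin Rec8 rose by 2.94, and Zglp1, a regulator of oogenic fate, by 2.50. Of the retinoic acid and BMP response, Zfp503 rose by 2.24, Gata2 by 2.08 and Msx1 by 1.94. The synaptonemal complex gene Sycp1 rose by 1.98 and the testis bromodomain gene Brdt by 1.59, and Dazl (1.08) and Ddx4 (0.70) rose further. Among imprinted genes Plagl1 rose by 2.53 and Ascl2, from a dim level, by 2.85. Kdm1b, a histone demethylase, rose by 1.40. Eif2s3y fell by 8 and Kdm5d by 4.21, both to dim levels, and Uba1y by 5.81, since the unsexed E11.5 samples held male cells. The Nodal inhibitor Lefty2 fell by 5.60, from 10.52 ± 0.25 at E11.5, and read 11.46 ± 0.30 in E12.5 males. A sex difference at E12.5 alone could give steps of either sex from the unsexed E11.5 cells without a change over time. Of the gonadal somatic genes, Lhx2 rose by 2.07 from a dim level (1.36 without E11.5 replicate 2) and Col3a1 fell by 1.63.

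In all, 338 genes passed for E12.5 females, 257 rising and 81 falling, 319 of them at least 2-fold, and 67 had a dim lower group. The rising share was 76.0%, and 60.9% with quantile normalization. Over all genes 8 of 31 meiosis genes rose (16 adjusted over the list alone, camera adjusted p = 8.10e-14, adjusted p = 0.0286 with an estimated correlation). Of 14 retinoic acid and BMP genes 5 rose (9 adjusted over the list alone, camera adjusted p = 1.21e-07, adjusted p = 0.0286 with an estimated correlation). Of the demethylation-dependent germline genes 6 rose (15 adjusted over the list alone, camera adjusted p = 7.34e-12, adjusted p = 0.148 with an estimated correlation). Of the markers of other cells, 1 of 18 gonadal somatic genes rose and 1 fell, 1 of 10 female supporting and 2 of 11 gut genes rose, and 1 of 13 immediate early and heat shock genes fell. Cited1, Rec8, Gata2, Plagl1 and Eif2s3y passed whichever array was left out. Meioc, a meiotic RNA regulator that rose by 2.06 from a dim level, Sycp1, Ddx4, Ascl2, Col3a1 and Kdm1b lost their calls without any one of the 4 arrays, and the rest of the named genes without at least 1. The count was 169 without E11.5 replicate 1, 64 without E11.5 replicate 2, 35 without E12.5 female replicate 1 and 23 without E12.5 female replicate 2. It was 40 with the compared arrays alone and 158 with the Gapdh difference as a covariate.

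The comparison of E12.5 males with E11.5 asked the same of the male side, against the same unsexed E11.5 arrays. Pmaip1, a pro-apoptotic BH3 gene, rose from 6.56 ± 0.22 to 10.20 ± 0.25 (log2 change 3.63, SE 0.35, adjusted p = 0.00238), and the homeobox gene Hesx1 from 5.23 ± 0.19 to 8.79 ± 0.52. The imprinted gene Phlda2 fell from 11.64 ± 0.15 to 8.04 ± 0.09, the serine protease inhibitor Serpinb9b from 8.45 ± 0.51 to 5.50 ± 0.54, and Id1, a target of BMP signals, from 9.99 ± 0.53 to 7.21 ± 0.17. Msx2 fell by 1.67 and Gata2 by 1.5. Piwil4, a piRNA pathway gene, rose by 2.12 from a dim level, Morc1, a repressor of transposons, fell by 1.75, and Dazl rose by 0.96. Germ cell and pluripotency genes Tfap2c (-1.16) and Klf2 (-1.38), the stress gene Gadd45a (-1.83) and the imprinted amino acid transporter Slc38a4 (-1.85) fell.

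For E12.5 males 183 genes passed, 60 rising and 123 falling, 179 of them at least 2-fold. Of 14 retinoic acid and BMP genes 4 fell (5 adjusted over the list alone, camera adjusted p = 4.88e-05, adjusted p = 0.156 with an estimated correlation). The male germ cell and piRNA list had 1 gene rising and 1 falling (6 and 1 adjusted over the list alone, camera adjusted p = 0.000478, adjusted p = 0.262 with an estimated correlation). The germline list had 1 rising (6 adjusted over the list alone, camera adjusted p = 4.88e-05, adjusted p = 0.517 with an estimated correlation). Of the markers of other cells, 1 of 12 male supporting genes (3 adjusted over the list alone) and 1 of 10 female supporting genes rose. Phlda2 alone passed whichever array was left out, and Gata2, Tfap2c and Klf2 lost their calls without any one of the 4. The count was 101 without E11.5 replicate 1, 18 without E11.5 replicate 2, 89 without E12.5 male replicate 1 and 2 without E12.5 male replicate 2. The compared arrays alone gave 0 genes with limma (1615 at an unadjusted p under 0.05, and 1704 in the fit of 12 arrays), and the Gapdh covariate gave 48.

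At E12.5 the sexes were compared directly. Lefty2 and Lefty1, targets and inhibitors of Nodal signals, were higher in males by 6.53 (11.46 ± 0.30 against 4.92 ± 0.19) and 5.43, Tdgf1 by 3.87, and Nodal by 1.61 from a dim female level. Stra8 was lower in males by a log2 difference of -5.58 (4.37 ± 0.71 against 9.95 ± 0.18), Phlda2 by -5.06, Id1 by -4.54 and Rec8 by -3.65. Gata2 differed by -3.58, Zglp1 by -2.48, and the imprinted genes Plagl1 and Slc22a18 by -2.83 and -3.00. Y-linked Eif2s3y (8.71) and Kdm5d (5.17), both from dim female levels, and Uba1y (6.80) were higher in males. So was Cst9 (4.89), from a dim female level. Cst9 is a cystatin fixed beforehand as a marker of male supporting cells. Of 435 genes that passed, 121 were higher and 314 lower in males, 392 of them at least 2-fold. The share higher in males was 27.8%, and 37.8% with quantile normalization. Of 14 retinoic acid and BMP genes 9 were lower (10 adjusted over the list alone, camera adjusted p = 1.56e-13, adjusted p = 0.011 with an estimated correlation). Of 31 meiosis genes 6 were lower (13 adjusted over the list alone, camera adjusted p = 1.25e-09, adjusted p = 0.0716 with an estimated correlation). Of 12 male supporting genes 2 were higher and of 11 gut genes 1 was lower in males (2 of each adjusted over the list alone).

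Named genes of the E12.5 sex difference passed whichever array was left out, except Cst9, lost without E12.5 male replicate 2 or E12.5 female replicate 2, and Tdgf1 and Nodal, lost without any one. The count was 96 without E12.5 female replicate 1, 93 without E12.5 female replicate 2, 139 without E12.5 male replicate 1 and 147 without E12.5 male replicate 2. It was 758 with the compared arrays alone and 1314 with array weights.

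**Figure D3:**
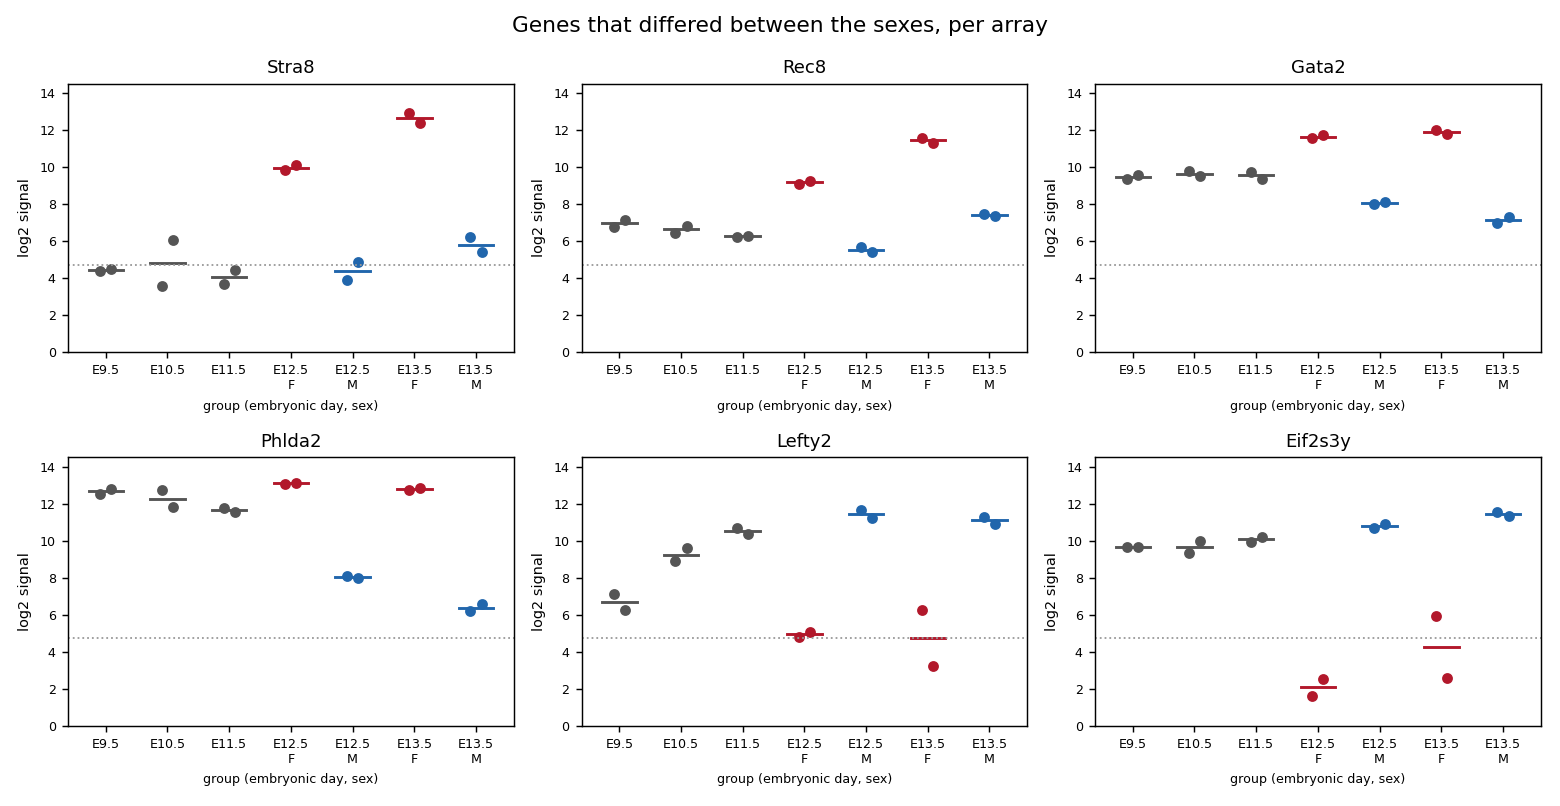
Log2 signal (vertical axes) of Stra8, Rec8, Gata2, Phlda2, Lefty2 and Eif2s3y in each array (points) with the group mean (lines), by group (horizontal axes; females red, males blue, unsexed grey; the dotted line is the table median, 4.72). Stra8 read 12.62 in E13.5 females and 5.80 in E13.5 males, and Phlda2 12.77 and 6.37.

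From E12.5 to E13.5 females raised genes of meiotic prophase. Zfp541, a chromatin factor of meiotic cells, rose from a dim 4.19 ± 0.34 to 8.47 ± 0.42 (log2 change 4.28, SE 0.39, adjusted p = 0.00235), and Fam90a1b by 4.03 from a dim level. Taf7l, a germ cell transcription factor subunit, rose from 6.24 ± 0.08 to 10.20 ± 0.52. Meiob, a single-strand DNA binding protein of recombination, rose by 3.85 from a dim level, Meioc by 3.40 and the telomere attachment gene Terb1 by 3.10. Tex101 rose by 2.73, and the synaptonemal complex genes Sycp1 and Sycp3 by 2.69 and 1.95. Stra8 was 2.67 higher (SE 0.67) and did not pass (adjusted p = 0.074). Troap, a spindle gene, fell by 2.98 and Plac8 by 2.44, both to dim levels, and the pluripotency factor Esrrb fell by 0.89. The cell cycle inhibitor Cdkn1c (1.27), Gadd45g (1.32) and Msx1 (1.24) rose.

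Of 341 genes that passed in this step of the females, 238 rose and 103 fell, and 305 were at least 2-fold. The rising share was 69.8%, and 61.0% with quantile normalization. Of 31 meiosis genes 18 rose (25 adjusted over the list alone, camera adjusted p = 1.99e-23, adjusted p = 0.0223 with an estimated correlation). Of the demethylation-dependent germline genes 5 rose (13 adjusted over the list alone, camera adjusted p = 1.62e-11, adjusted p = 0.231 with an estimated correlation). Of 18 pluripotency genes 1 fell (10 adjusted over the list alone, median change -0.89, camera adjusted p = 3.28e-08, adjusted p = 0.231 with an estimated correlation). Of 15 germ cell identity genes 8 were lower adjusted over the list alone (median change -0.46, camera adjusted p = 0.000159, adjusted p = 0.231 with an estimated correlation). The 11 endothelial genes had a median change of -0.60 (camera adjusted p = 0.0159, adjusted p = 0.231 with an estimated correlation), with none called. Of the gonadal somatic genes Nr2f1 rose by 2.55 from a dim level, and of the immediate early genes Ier3 fell by 1.23. None of the 17 called genes named here kept its call whichever array was left out. The count was 11 without E12.5 female replicate 1, 0 without E12.5 female replicate 2 (limma, with 1722 genes at an unadjusted p under 0.05), 1 without E13.5 female replicate 1 and 89 without E13.5 female replicate 2. Leaving out the 2 arrays with a Gapdh difference above 3, an alternative chosen after the data were seen, gave 15, and the Gapdh covariate 140. Taf7l lost its call only without E12.5 female replicate 2.

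Males over the same day raised some of the same genes. Upp1, a uridine phosphorylase, rose by 5.04 (SE 0.58, adjusted p = 0.00312) and Asb9, a ubiquitin ligase adaptor, by 4.83, both from dim levels. Carbonic anhydrase Car2 fell by 2.74 to a dim level and hexokinase Hk1 by 2.53. Taf7l rose from 5.16 ± 0.01 to 8.03 ± 0.25, Sycp1 from 6.88 ± 0.23 to 9.52 ± 0.07, and Brdt by 1.66. Sycp2 rose by 2.31, Msh4 by 1.95 from a dim level and Rec8 by 1.87. Of 13 cell cycle inhibitors 3 rose and 1 fell (3 and 1 adjusted over the list alone, camera adjusted p = 0.478): Cdkn1c rose by 1.64, Cdkn2b by 1.49 and Rb1 by 1.13, and Gadd45a fell by 2.15. The histone methyltransferase gene Ehmt2 rose by 0.77, and Tfap2c fell by 0.95, Slc38a4 by 1.53 and Phlda2 by 1.67. Markers of other cells moved too: Col3a1 rose by 1.61 and Cyp17a1, a steroidogenic enzyme, by 2.37 from a dim level, and the median change of the 18 gonadal somatic genes was 0.44 (camera adjusted p = 0.0064, adjusted p = 0.22 with an estimated correlation).

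In males 381 genes passed, 248 rising and 133 falling, 357 of them at least 2-fold. The rising share was 65.1%, against 53.8% with quantile normalization. Without the arrays with a Gapdh difference above 3, too few genes passed to read an excess in either direction. Of the germline list 4 rose (13 adjusted over the list alone, camera adjusted p = 2.73e-11, adjusted p = 0.226 with an estimated correlation), and of the meiosis list 6 rose (12 adjusted over the list alone, camera adjusted p = 5.39e-09, adjusted p = 0.22 with an estimated correlation). Of the male germ cell and piRNA list 6 were higher adjusted over the list alone (camera adjusted p = 0.00417, adjusted p = 0.226 with an estimated correlation). The pluripotency list was lower by camera (median change -0.27, adjusted p = 0.0179, adjusted p = 0.51 with an estimated correlation), as was the S phase list (median change -0.16, adjusted p = 0.00783, adjusted p = 0.491 with an estimated correlation). Upp1, Taf7l and Rec8 passed whichever array was left out. Of the 20 called genes named here, 12 lost their calls with the Gapdh covariate. Nearly all lost them without the arrays with a Gapdh difference above 3. Hk1, Brdt, Msh4, Rb1, Ehmt2, Tfap2c, Col3a1 and Phlda2 lost their calls without any one of the 4 compared arrays. The count was 16 without E12.5 male replicate 1, 167 without E12.5 male replicate 2, 48 without E13.5 male replicate 1 and 58 without E13.5 male replicate 2. It was 13 without the arrays with a Gapdh difference above 3 and 97 with the Gapdh covariate. The 2 sexes, which share no arrays in these steps, had 48 rising genes in common where independent lists would share 3.24, and 28 falling genes where they would share 0.753. In opposite directions 0 genes passed with limma, where 3.14 would be shared. Both steps took each gene's spread from the same fit of 12 arrays. A gene of low spread can therefore pass in both, and the figures for independent lists may be too low. The independent lists leave out what arrays of 1 number share: steps taken from single arrays correlated across genes by 0.606 and 0.564 with the same number in both sexes, and by 0.364 and 0.42 with different numbers. With replicate number as a block 47 rising and 26 falling genes were shared (2.49 and 0.652 for independent lists). Without the 2 arrays with a Gapdh difference above 3, too few genes passed in each sex to read an overlap. These checks of the overlap were chosen after the data were seen.

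At E13.5 the sexes differed in 1854 genes, 763 higher and 1091 lower in males, 1446 of them at least 2-fold. The share higher in males was 41.2%, 45.3% with quantile normalization and 49.0% with median centring, so the excess of lower genes depends on the scaling. Stra8 read 5.80 ± 0.57 in males and 12.62 ± 0.38 in females (log2 difference -6.82, SE 0.67, adjusted p = 0.00017), and Phlda2 6.37 ± 0.28 and 12.77 ± 0.07. Gata2 differed by -4.75 and Id1 by -4.27, and the meiosis genes Meiob (to a dim male level), Meioc and Rec8 by -4.73, -4.22 and -4.04. Eif2s3y was higher in males by 7.17 from a dim female level, Lefty2 by 6.36 and Lefty1 by 5.20. Pmaip1 was higher by 6.02 (11.68 ± 0.22 against 5.66 ± 0.66), and the Nodal co-receptor Tdgf1 by 5.05 from a dim female level. The pluripotency gene L1td1 was 1.31 and the germ cell gene Dppa4 0.64 higher in males, and Tfap2c was lower (-1.16). Among imprinted genes Plagl1 (-3.07), Slc22a18 (-3.04) and Grb10 (-1.82) were lower and Mest, a hydrolase gene, was higher (2.89) in males. Of the cell cycle inhibitors Gadd45a (-2.84) and Cdkn2d (-2.33) were lower in males, as was Ccne1 (-0.80), a cyclin of S phase entry, while the mitotic kinase gene Aurkb was higher (0.77). Of 12 markers of male supporting cells, Cst9 (6.44) and Ptgds (3.41) were higher in males, both from dim female levels (3 adjusted over the list alone, camera adjusted p = 0.0487, adjusted p = 0.29 with an estimated correlation), and Amh read 6.01 ± 0.03 against 5.94 ± 0.33. Of 10 female supporting genes 4 were lower in males, among them Irx3 (-4.11, to a dim level). Of 18 gonadal somatic genes 2 were higher, among them Cyp17a1 (2.64, from a dim female level), and 2 lower, Lhx2 (-3.00) and Nr2f1 (-2.97, to a dim level). Of 11 gut genes 2 were lower (3 adjusted over the list alone, camera adjusted p = 0.0487, adjusted p = 0.234 with an estimated correlation), among them the homeobox gene Cdx2, at 1.46 ± 0.26 in males, a dim level, and 7.60 ± 0.33 in females. Of 13 immediate early and heat shock genes 4 were higher in males (camera adjusted p = 0.0487, adjusted p = 0.29 with an estimated correlation).

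The E13.5 sex difference covered 20 of 31 meiosis genes, all lower in males (25 adjusted over the list alone, camera adjusted p = 9.31e-16, adjusted p = 0.031 with an estimated correlation). It covered 11 of 14 retinoic acid and BMP genes, also lower (12 adjusted over the list alone, camera adjusted p = 3.69e-13, adjusted p = 0.0126 with an estimated correlation). The sex difference at E12.5 has its group means from other arrays. With it, the E13.5 sex difference shared 102 genes higher in males (5.07 for independent lists) and 252 lower (18.8). The spread per gene came from the same fit in both, so these independent figures may be too low. Without the 2 arrays with a Gapdh difference above 3 fewer genes were shared, still above the independent figures. L1td1, Tfap2c, Dppa4 and Cdkn2d lost their calls without at least 1 array, and Ccne1 and Aurkb without any one. The count was 912 without E13.5 male replicate 1, 945 without E13.5 male replicate 2, 919 without E13.5 female replicate 1 and 1046 without E13.5 female replicate 2, and 409 without the arrays with a Gapdh difference above 3.

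E13.5 female replicate 1 carried a low signal of male genes, a comparison made after the data were seen. Eif2s3y read 5.93 in replicate 1 and 2.58 in replicate 2 of the E13.5 females, against 11.43 in E13.5 males. Uba1y read 7.96 and 5.07, Lefty2 6.26 and 3.23, and Lefty1 8.22 and 6.61. On the linear scale the excess came to 2% of the male level for Eif2s3y, 4.39% for Uba1y, 3.06% for Lefty2 and 3.20% for Lefty1. Of 7 genes picked on the E12.5 arrays alone (over 3 higher in males, with a male mean over 9), 6 were higher in replicate 1, with a median difference of 1.61, where the upper limit of 10000 random lists matched on level, at a two-sided level of 0.05, was 0.49. The same genes differed by a median of 0.21 between the E13.5 male arrays. Tdgf1 did not differ (3.57 and 3.61), nor did the dimmer Kdm5d (1.44 and 1.76).

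Whether the sex difference itself changed from E12.5 to E13.5 was tested as an interaction. Tgfbr3, a co-receptor of TGF beta signals, changed by 3.18 (SE 0.36, adjusted p = 0.0289), from 4.74 ± 0.27 in males and 5.18 ± 0.17 in females at E12.5 to 7.58 ± 0.03 and 4.84 ± 0.24 at E13.5. Rhox9, a reproductive homeobox gene, changed by -1.95 (SE 0.22, adjusted p = 0.0289), from 12.39 ± 0.21 and 13.11 ± 0.05 to 10.21 ± 0.13 and 12.88 ± 0.07. These 2 genes passed with limma, and 1350 had an unadjusted p under 0.05. Neither passed when any one of the 8 arrays was left out, with replicate number as a block, with the Gapdh covariate, or without the arrays with a Gapdh difference above 3, each of which gave 0 genes with limma (993 to 1422 at an unadjusted p under 0.05). The meiosis list changed by a median of -0.58 (camera adjusted p = 4.46e-07, adjusted p = 0.327 with an estimated correlation).

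**Figure D4:**
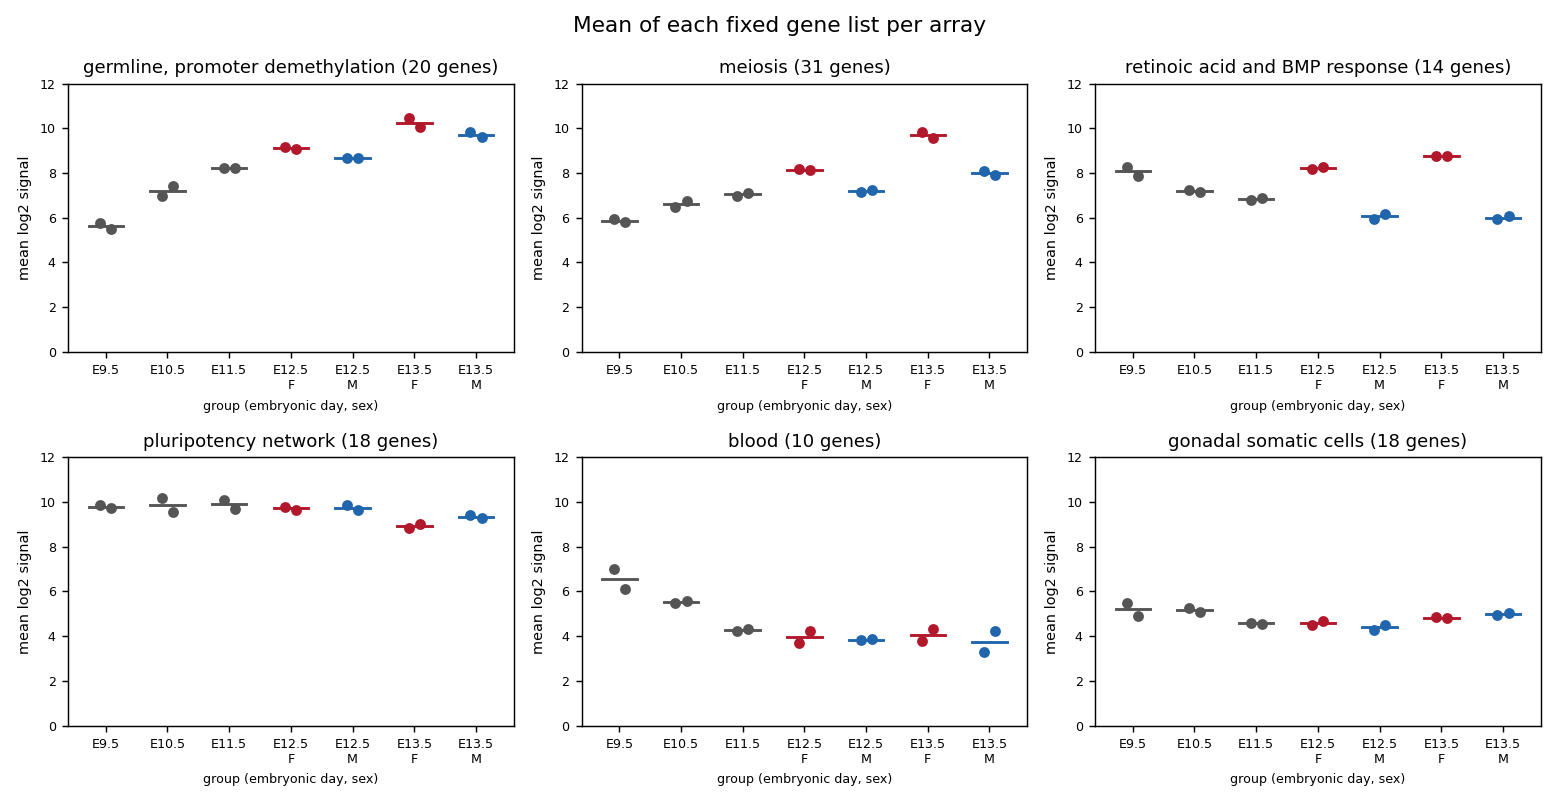
Mean log2 signal (vertical axes) of 6 gene lists in each array (points) with the group mean (lines), by group (horizontal axes; females red, males blue, unsexed grey). The meiosis list read 9.84 and 9.57 in E13.5 females and 8.07 and 7.93 in E13.5 males.

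The comparison of E13.5 females with E10.5 spans the whole period in 1 protocol. The E10.5 cells were not sexed and held male cells, so a sex difference at E13.5 alone could contribute to changes of either sex against E10.5. Stra8 rose from 4.80 ± 1.73 to 12.62 ± 0.38 (log2 change 7.82, SE 0.67, adjusted p = 4.36e-05), Ccdc172 by 6.78, Sp5, a transcription factor, by 6.07, Taf7l by 5.74 and Meioc by 5.73, all 4 from dim levels, Sycp1 by 5.47 and Tex101 by 5.21. Rec8 rose by 4.82, Dazl by 4.27 and Ddx4 by 2.06. Eif2s3y fell by 5.41 to a dim level, Stat4, a cytokine signal transducer, by 5.12, and the embryonic haemoglobin gene Hba-x by 4.99 to a dim level. Of the pluripotency network Tdgf1 fell by 4.20 to a dim level, Nanog by 2.10, L1td1 by 1.79, Esrrb by 1.43 and Pou5f1 by 0.59. Tdgf1 read 7.79 ± 1.51 at E10.5 and 8.64 ± 0.59 in E13.5 males, so its fall cannot be told apart from the sex difference. Germ cell identity genes Ifitm3 (-1.87) and Tfap2c (-1.26) fell. Kdm1b rose by 3.05, the histone methyltransferase gene Ehmt1 by 1.25, and the repair glycosylase gene Neil3 by 1.82, while Gadd45a fell by 1.78. Among imprinted genes Mest fell by 2.40, Plagl1 rose by 2.15 and Ascl2, from a dim level, by 3.99. Msx1 rose by 2.98 and Cdkn2b, from a dim level, by 2.81, and Aurkb fell by 1.25. Of the gonadal somatic genes Lhx2 rose by 3.72 from a dim level and the collagen gene Col3a1 fell by 3.52. The endothelial gene Emcn fell by 2.73 to a dim level, the blood gene Hbb-bh1 by 2.68 and the stress gene Ier3 by 3.91.

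In this comparison 3248 genes passed, 2085 rising and 1163 falling, 2436 of them at least 2-fold, and 553 had a dim lower group. The rising share was 64.2%, and 53.8% with quantile normalization. Of 31 meiosis genes 27 rose (29 adjusted over the list alone, camera adjusted p = 2.98e-24, adjusted p = 0.0203 with an estimated correlation). Of 20 demethylation-dependent germline genes 19 rose (20 adjusted over the list alone, camera adjusted p = 1.59e-20, adjusted p = 0.0731 with an estimated correlation). Of 18 pluripotency genes 8 fell (8 adjusted over the list alone, camera adjusted p = 1.94e-05, adjusted p = 0.136 with an estimated correlation), and of 15 germ cell identity genes 4 fell (4 adjusted over the list alone). Of 14 retinoic acid and BMP genes 6 rose (7 adjusted over the list alone). Of the imprinted genes 2 of 22 paternally expressed rose and 6 fell (2 and 8 adjusted over the list alone), and 3 of 19 maternally expressed rose and 1 fell (3 and 1). Of 23 histone modifiers 3 rose and 5 fell, of 19 base excision repair genes 2 rose and 3 fell, of 23 genes of G2 and mitosis 2 rose and 3 fell, and of 13 cell cycle inhibitors 5 rose and 1 fell, with the same counts adjusted over each list alone. Of 26 S phase genes 1 fell, and none adjusted over the list alone. Of the markers of other cells, 7 of 11 endothelial genes fell (8 adjusted over the list alone, camera adjusted p = 4.44e-05, adjusted p = 0.0931 with an estimated correlation), 2 of 10 blood genes fell, 4 of 13 immediate early and heat shock genes fell, 1 of 18 gonadal somatic genes rose and 3 fell, and 4 of 10 female supporting and 4 of 11 gut genes rose. Among these gut genes was Trap1a, chosen after its values were seen, which already read 10.12 ± 0.23 at E10.5. Its rise alone does not show RNA of gut cells. Trap1a was also the gut gene that rose in E13.5 males against E10.5 and in E10.5 against E9.5.

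Ifitm3 and Hells lost their calls without E13.5 female replicate 1, and the chromatin factor Ctcf, which fell by 0.95, without any one of the 4 arrays. Of the 38 called genes named for E13.5 females against E10.5, 35 passed whichever array was left out. The count of passing genes was 1902 without E13.5 female replicate 1, 2019 without the 2 arrays with a Gapdh difference above 3 (1 female and 1 male), and 1022 with the compared arrays alone.

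E13.5 males against the unsexed E10.5 cells gave 2319 genes, 1368 rising and 951 falling, 1807 of them at least 2-fold. The rising share was 59.0%, and 50.3% with quantile normalization, so the excess of rising genes depends on the scaling. Frmpd1, a scaffold gene, rose by 7.98 (SE 0.74, adjusted p = 7.57e-05), Cst9 by 7.41, both from dim levels, and Pmaip1 by 6.79. Phlda2 fell by 5.89 and the neuropilin gene Nrp2 by 5.88 to a dim level. Sycp1 rose by 4.36, Dazl by 4.26, Mael, a piRNA pathway gene, by 3.77 and Ddx4 by 1.91. Sycp2 rose by 4.19, Piwil4 by 4.64 from a dim level and Lefty1 by 3.30. Tfap2c fell by 2.42, the alkaline phosphatase gene Alpl by 2.21, Rex2 by 2.57 with both levels dim and Esrrb by 1.23, while Pou5f1 differed by -0.34 and did not pass (adjusted p = 0.116). Kdm1b rose by 2.53 and Ehmt2 by 0.91, and Cdkn2b, from a dim level, and Rb1 rose by 3.47 and 1.68. Gadd45a fell by 4.62, the S phase genes Rrm2 and Ccne1 by 1.81 and 1.24, Gata2 by 2.50 and Msx2 by 2.43. Rarb fell by 2.62, from 6.08 ± 1.31 at E10.5, where the arrays differed widely, to a dim 3.46 ± 0.91. Imprinted Slc38a4 fell by 3.83 and Grb10 by 3.43, while Ascl2 rose by 4.98 from a dim level. Ptgds rose by 3.85 from a dim level. Rspo1, a marker of female supporting cells, rose by 4.16. The blood gene Hba-x fell by 4.96 and the gut gene Cdx2 by 4.04, both to dim levels. The gonadal somatic genes Nr2f1 and Col3a1 fell by 2.90, to a dim level, and 2.55, the endothelial gene Emcn by 2.07 to a dim level and the stress gene Ier3 by 2.44.

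By list, 18 of 20 demethylation-dependent germline genes rose in E13.5 males against E10.5 (20 adjusted over the list alone, camera adjusted p = 7.39e-21, adjusted p = 0.0388 with an estimated correlation). Of 31 meiosis genes 19 rose (20 adjusted over the list alone) and of 18 male germ cell and piRNA genes 11 rose and 1 fell (15 and 1 adjusted over the list alone). Of 14 retinoic acid and BMP genes 7 fell (8 adjusted over the list alone, camera adjusted p = 6.67e-06, adjusted p = 0.0388 with an estimated correlation). Of 26 S phase genes 4 fell (4 adjusted over the list alone, camera adjusted p = 0.0111, adjusted p = 0.357 with an estimated correlation). Of 12 male supporting cell genes 2 rose, of 18 gonadal somatic genes 1 rose and 3 fell, and of 10 blood genes 2 fell (4 adjusted over the list alone). Of 10 female supporting genes 2 rose and 1 fell, of 11 gut genes 1 rose and 1 fell, and of 13 immediate early and heat shock genes 2 fell. Of 11 endothelial genes 4 fell (6 adjusted over the list alone, camera adjusted p = 0.00358, adjusted p = 0.222 with an estimated correlation). Emcn, Rex2, Rrm2 and Rarb lost their calls without at least 1 array, with Rrm2 at -0.82 without E10.5 replicate 1, and the other 33 called genes named here passed whichever array was left out. The count was 1307 without E13.5 male replicate 1, 1294 without E13.5 male replicate 2, 1116 without the 2 arrays with a Gapdh difference above 3 (1 of them female), and 578 with the compared arrays alone.

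Whether the genes of DNA methylation changed while imprints are erased was asked over the same span. Of 17 genes of DNA methylation and hydroxymethylation, 1 rose and 2 fell in E13.5 females against E10.5. Hells, a chromatin remodeller that maintains methylation, rose by 1.21, with a value of 0.77 without E10.5 replicate 1 and no call without E13.5 female replicate 1. Mbd3 fell by 0.98 and Ctcf by 0.95. In E13.5 males 1 gene of the list fell, and none adjusted over the list alone. The maintenance methyltransferase gene Dnmt1 stayed bright, at 11.93 ± 0.43 at E10.5, 12.34 ± 0.16 in E13.5 females and 11.94 ± 0.04 in E13.5 males. Its difference was 0.41 in females (95% interval -0.10 to 0.92, adjusted p = 0.284) and 0.01 in males (-0.50 to 0.53, adjusted p = 0.982). Uhrf1, which guides Dnmt1 to replicated DNA, differed by 1.79 in females (0.14 to 3.44, adjusted p = 0.139) and 1.26 in males (-0.39 to 2.91, adjusted p = 0.34), from 5.32 ± 1.79 at E10.5, where the arrays differed widely; with 1 array left out it ranged from 0.52 to 3.05 in females and from 0 to 2.53 in males. The de novo methyltransferase genes Dnmt3a (-0.35 and 0.23) and Dnmt3b (0.90 and 0.46) did not pass in females or males against E10.5. Nor did the dioxygenase genes Tet1 (-0.68 and 0.19) and Tet2 (1 and 0.43). Between these ages, Dnmt3b read 5.20 ± 1.25 at E11.5 and 7.70 ± 0.04 in E12.5 males (log2 change 2.51, limma adjusted p = 0.0627). It was 1.70 higher in E12.5 females than at E11.5 (adjusted p = 0.168). From E12.5 to E13.5 in males it fell by 1.58 (adjusted p = 0.192), and none of these steps passed. Dnmt3l was dim in E10.5 cells (1.71 ± 2.24) and in both sexes at E13.5 (1.07 ± 0.17 and 3.90 ± 0.56), and Dppa3 differed by 0.02 and 0.27. With quantile normalization the differences of Dppa3 in females and of Dnmt1 in males changed sign, to -0.07 and -0.06. With the mean of all probe sets those of Tet1 and Tet2 in females did, to 0.19 and -0.27, and the other probe set of Tet1 went the opposite way with an unadjusted p under 0.05. A difference that did not pass is not shown to be absent with 2 arrays per group.

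**Figure D5:**
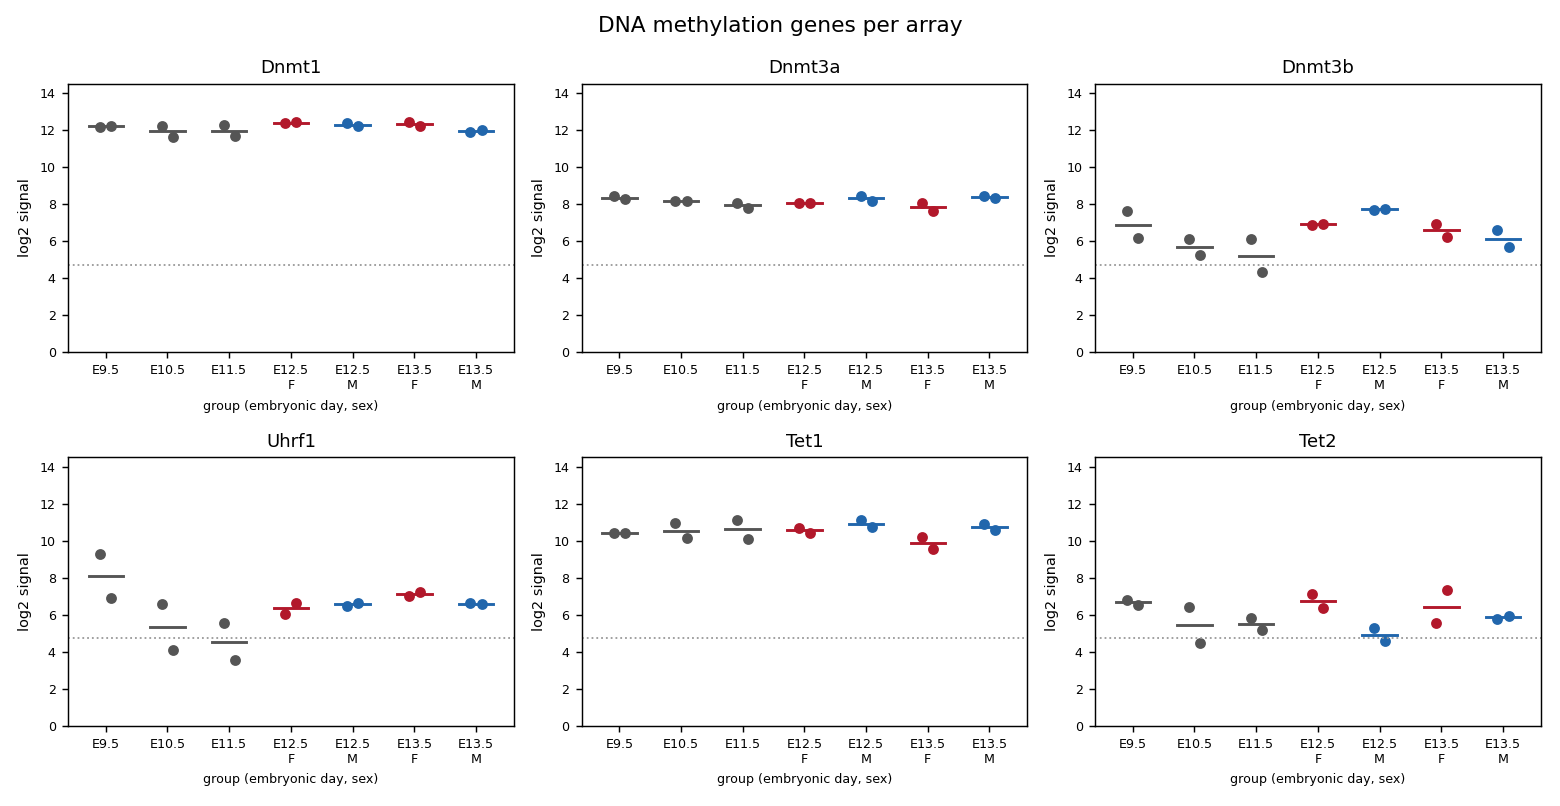
Log2 signal (vertical axes) of Dnmt1, Dnmt3a, Dnmt3b, Uhrf1, Tet1 and Tet2 in each array (points) with the group mean (lines), by group (horizontal axes; females red, males blue, unsexed grey; the dotted line is the table median, 4.72). Dnmt1 read 11.93 at E10.5, 12.34 in E13.5 females and 11.94 in E13.5 males.

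The comparison of E10.5 with E9.5 joins 2 protocols: the E9.5 cDNA had 22 cycles of amplification against 12, came from another strain background and from an earlier study, so age and protocol could not be told apart. Dazl was higher at E10.5, at 9.07 ± 0.16 against a dim 4.70 ± 1.42 (log2 change 4.36, SE 0.45, adjusted p = 0.00121). Asz1 and Hormad1, genes of the piRNA pathway and of meiosis, rose by 2.89 and 2.84, Mael by 2.59, Mov10l1 by 2.21 and Piwil2 by 1.94. The germ cell genes Dppa2 and Dppa4 rose by 1.69 and 1.30. Nepn fell by 5.16 and Hoxb1, a gene of axial patterning, by 3.72, both to dim levels, Greb1l fell by 3.78, and the haemoglobin genes Hbb-bh1 and Hba-x by 3.57 and 2.96. Grb10 fell by 1.74, the retinoic acid binding protein gene Crabp2 by 2.69 and Msx1 by 1.24. With limma 193 genes passed, 130 rising and 63 falling, 182 of them at least 2-fold. Of the 20 demethylation-dependent germline genes 12 rose (16 adjusted over the list alone, camera adjusted p = 5.42e-22, adjusted p = 0.0667 with an estimated correlation), and 6 of 18 male germ cell and piRNA genes rose (7 adjusted over the list alone). Of the 10 blood genes 2 fell (3 adjusted over the list alone), and of 11 gut genes 1 rose and 2 fell (1 and 4 adjusted over the list alone, camera adjusted p = 0.028, adjusted p = 0.128 with an estimated correlation).

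Of the 16 genes named for E10.5 against E9.5, 8 passed whichever array was left out: Dazl, Asz1, Hormad1, Mael, Mov10l1, Greb1l, Dppa2 and Dppa4. The count was 66 without E9.5 replicate 1, 266 without E9.5 replicate 2, 1927 without E10.5 replicate 1 and 51 without E10.5 replicate 2. The rising share was 67.4%, and 26.6% of the 1927 genes rose. The 4 compared arrays alone gave 0 genes with limma (1128 at an unadjusted p under 0.05, and 2932 in the fit of 14 arrays), and array weights gave 48.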

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

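The results here come from the planned test of whether the difference between males and females changed from E12.5 to E13.5, and none of these tests was chosen after the result was seen. The interaction called 2 genes. Tgfbr3, a co-receptor of TGF beta signals, changed by 3.18: it was higher in E13.5 males (7.58 ± 0.03, SD, n = 2) than in E13.5 females (4.84 ± 0.24), and E12.5 levels were 4.74 ± 0.27 and 5.18 ± 0.17. Rhox9, a reproductive homeobox gene, changed by -1.95: it read 10.21 ± 0.13 in E13.5 males and 12.88 ± 0.07 in E13.5 females, and 12.39 ± 0.21 and 13.11 ± 0.05 at E12.5. Both calls ended when any one of the 8 arrays was left out, and with replicate number as a block, where limma gave 0 genes and 1422 at an unadjusted p under 0.05.

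Of the 22 gene lists, 4 were called by camera in the same test, and none of the 4 with an estimated correlation. The median change of the sex difference was 0.422 for the pluripotency network (adjusted p = 0.0161, adjusted p = 0.535 with an estimated correlation) and 0.355 for histone modifiers (adjusted p = 0.0161, adjusted p = 0.38 with an estimated correlation). It was -0.575 for meiosis (adjusted p = 4.46e-07, adjusted p = 0.327 with an estimated correlation), where 7 of 31 genes were lower adjusted over the list alone. For the retinoic acid and BMP response it was -0.77 (adjusted p = 0.0126, adjusted p = 0.327 with an estimated correlation), with 2 of 14 genes lower adjusted over the list alone.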

How the results depend on the processing

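The settings with the Gapdh difference and the crossed replicate block were chosen after the data were seen, and the others were planned. Changes are counts of genes passing unless said otherwise, and the cause was not tested except where the setting removes arrays or changes the number of genes tested. For E11.5 against E10.5 (14 genes) the count was 29 with quantile normalization, 22 with median centring, 9 without genes whose mean lay below that of the median gene (9097 kept), 31 with a floor, 0 with the compared groups alone (limma, 737 at an unadjusted p under 0.05), 9 with all 14 arrays and 1 with array weights. With the mean of all probe sets it was 224 for E12.5 females and 110 for E12.5 males against E11.5, 225 for E13.5 against E12.5 females and 0 for the interaction. Without the intensity trend it was 125 and 79 for E12.5 females and males against E11.5, 165 and 211 for the E13.5 steps of females and males, 279 for the E12.5 sex difference, 0 for the interaction and 120 for E10.5 against E9.5. With the compared groups alone it was 40 for E12.5 females and 0 for E12.5 males against E11.5, 201 for E13.5 against E12.5 males, 1022 and 578 for E13.5 females and males against E10.5, 758 for the E12.5 sex difference, 0 for the interaction and 0 for E10.5 against E9.5. Array weights gave 741 for E12.5 females against E11.5, 1023 and 796 for the E13.5 steps of females and males, 1314 for the E12.5 sex difference, 26 for the interaction and 48 for E10.5 against E9.5, and the floor gave 51 for the interaction. The Gapdh covariate gave 158 and 48 for E12.5 females and males against E11.5, 140 and 97 for the E13.5 steps of females and males, and 0 for the interaction. Without the arrays with a Gapdh difference above 3 the counts were 15 and 13 for those steps, 2019 and 1116 for E13.5 females and males against E10.5, 409 for the E13.5 sex difference and 0 for the interaction. Where the interaction count was 0 in these settings, limma gave 1016 to 1853 genes at an unadjusted p under 0.05, and the count was 1615 for E12.5 males against E11.5 and 1128 for E10.5 against E9.5 with the compared groups alone.

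With 1 array left out, counts ranged from 1 to 39 for E11.5 against E10.5, 23 to 169 and 2 to 101 for E12.5 females and males against E11.5, 0 to 89 and 16 to 167 for the E13.5 steps of females and males, 1902 to 3367 and 1294 to 2685 for E13.5 females and males against E10.5, 93 to 147 for the E12.5 and 912 to 1046 for the E13.5 sex difference, 0 to 0 for the interaction, and 51 to 1927 for E10.5 against E9.5. The lone array of a group was then assumed to vary like the other groups. Of 242 list tests 77 were called, 20 with an estimated correlation and 69 with the replicate block. The replicate block gave 0 genes for the interaction and otherwise counts within 1.5 times those reported. Among named genes it ended 3 calls for E12.5 females against E11.5, 2 for E10.5 against E9.5 and 2 for the interaction. It ended 1 call each for the E13.5 steps of females and males and the E13.5 sex difference. Replicate differences correlated above 0.1 in 7 of 15 pairs of groups and below -0.1 in 6, so the numbers do not pair the samples of all groups. The highest values were 0.693 for E10.5 with E11.5, 0.671 for the sexes at E13.5 and 0.422 at E12.5, which leaves a pairing of some groups open; with the block the sex differences had 387 and 1892 genes. With the numbers of 1 group swapped, the block gave 3326 and 2236 genes for E13.5 females and males against E10.5 and 262 for E12.5 females against E11.5.

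The 218 called results for named genes kept their sign in all 3443 settings, and 567 settings ended a call: 265 of 880 that left out an array and 302 of 2563 others, 79 of these with the compared groups alone. Where both arrays of a group lie above both of the other, as the naming rule asks of the largest changes, leaving out 1 array cannot reverse the sign. Named genes that were not called changed sign in 16 of 297 settings and passed in 11. Against E10.5 in females, Dppa3 was -0.07 with quantile normalization, -0.06 with median centring, -0.05 without E13.5 female replicate 1 and -0.06 without E10.5 replicate 2; Tet1 was 0.19 and Tet2 -0.27 with the mean of all probe sets, and Dnmt3l was 0.94 without E10.5 replicate 2. With 1 array left out Dppa3 ranged from -0.06 to 0.11, Dnmt3l from -2.23 to 0.94, Dnmt1 from 0.1 to 0.71, Dnmt3a from -0.56 to -0.13, Dnmt3b from 0.49 to 1.32, Uhrf1 from 0.52 to 3.05, Tet1 from -1.1 to -0.26 and Tet2 from 0.03 to 1.96. In males, Dnmt1 was -0.06 with quantile normalization, -0.29 without E10.5 replicate 2, -0.02 without E13.5 male replicate 2 and -0.01 without the 2 arrays with a Gapdh difference above 3, Dnmt3a was -0.07 with the mean of all probe sets, and Dnmt3b was 0 without E13.5 male replicate 1. Without E10.5 replicate 2, Uhrf1 was 0, Tet1 -0.23 and Tet2 -0.53. With 1 array left out the male values ranged from -0.29 to 0.32 for Dnmt1, 0 to 0.92 for Dnmt3b, 0 to 2.53 for Uhrf1, -0.23 to 0.61 for Tet1 and -0.53 to 1.4 for Tet2. Pseudocounts were not run, since the values were already log2. Signal over background limits dim genes: 553 of the 3248 genes for E13.5 females against E10.5 had a dim lower group.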

Other observations

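Of the tests below, those on marker RNA and imprinted genes between the E9.5 arrays, on arrays of the same number, on RNA integrity and on male supporting cells were chosen only after the result was seen, and so was the comparison of X-linked genes. Genes on the X chromosome (618 genes placed by the RefSeq table of GRCm38.p6, 300 of them above the median level) were lower in males. Among the brighter genes the median male minus female difference was -0.44 at E12.5 (-0.04 for other genes) and -0.47 at E13.5 (0.01 for other genes). At E12.5, 1 X-linked gene was higher and 44 were lower in males (camera adjusted p = 9.68e-05, adjusted p = 0.0193 with an estimated correlation), and at E13.5 16 and 109 (camera adjusted p = 8.91e-05, adjusted p = 0.0193 with an estimated correlation). From E12.5 to E13.5, 23 rose and 3 fell in females (median 0.18, 0.01 for other genes; camera adjusted p = 0.0162, adjusted p = 0.0684 with an estimated correlation), and 21 rose and 10 fell in males (median 0.13, 0.07 for other genes; camera adjusted p = 0.309, adjusted p = 0.327 with an estimated correlation). From E11.5 to E12.5, 26 rose and 6 fell in females (camera adjusted p = 0.0874, adjusted p = 0.141 with an estimated correlation), and 1 rose and 10 fell in males (median -0.16, 0.04 for other genes; camera adjusted p = 0.0132, adjusted p = 0.0684 with an estimated correlation). The E11.5 cells were not sexed, so the sex difference at E12.5 alone could give opposite steps from E11.5 without a change over time. Whether these steps differ between the sexes was not tested for the X chromosome.

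Imprinted genes were lower at E11.5 than at E10.5 beside markers of blood and mesenchyme, 7 of 41 adjusted over the lists alone: Cdkn1c, Dlk1, Gnas, Grb10, Magel2, Mest and Plagl1. RNA of other cells carried through the sort may contribute, although a sort on stella-EGFP should remove such cells. The test used the 2 arrays of E9.5, which had another protocol and no described sort, so it does not show RNA passing the sort. These arrays differ in Hbb-bh1 by 1.95, Col3a1 by 1.41, Col1a2 by 1.1, Hba-x by 0.74 and Hbb-y by 0.57 (mean of 39 markers 6.16 and 5.57). The E10.5 arrays differ in the same markers by 0.66, 0.74, -0.06, 0.7 and 0.3. Between the E9.5 arrays the 7 imprinted genes differed by a median of 0.76. This lies above the upper limit (0.5, at a two-sided level of 0.05) of 10000 random lists matched on level. A change in the germ cells themselves also stays open. With the marker mean as a covariate, the median change was -1.37 (median SE 0.64), against -0.93 without it. This test cannot decide, since the genes were picked because they fell on these same arrays. The marker mean also followed the comparison, at 5.72 and 5.49 in E10.5 and 4.88 and 4.87 in E11.5. Both remain candidate explanations, and the tests do not divide the change between them.

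Differences between replicates correlated across genes between groups. A batch shared by all arrays of the same number is argued against by 6 of 15 pairs of groups with correlations below -0.1, beside 7 above 0.1, while a source shared by some of the groups stays open (0.693 for E10.5 with E11.5, 0.671 for the sexes at E13.5 and 0.422 at E12.5). RNA integrity as a source shared by all groups is argued against by a correlation of -0.494 between E10.5 and E13.5 females. In both of these groups replicate 2 has the larger Gapdh difference. The same holds in E10.5 with E11.5 (0.693) and the sexes at E13.5 (0.671), so RNA integrity as a source for some groups stays open. Replicates of slightly different embryonic age may play a part, which stays open. The highest absolute correlation of a replicate difference with an age change on other arrays was 0.456 and the lowest 0.0345 over 4 groups. It was 0.29 for E10.5 and -0.456 for E11.5, opposite in sign and taken with different age changes. The replicate differences of these groups correlate by 0.693. Genes are not independent replicates in these correlations.

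Cst9 and Ptgds, markers of male supporting cells, were higher in E13.5 male arrays. RNA of such cells carried through the sort could raise both, and this stays open: the 10 other members of the list, 6 higher and 4 lower, differed by a median of 0.13, beside 3.41 for Ptgds, but their levels vary and several are dim. Erbb4 (2.38, SE 1.09) and Dhh (0.79, adjusted p = 0.0817) were higher in males without passing, and Amh (0.08), Sox9 (-0.52) and Aard (-0.39) did not pass. No biological explanation was tested for this pattern.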
